A study of Saccharomyces cerevisiae with 7 samples.

How the data were processed

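Genomic DNA of 7 Saccharomyces cerevisiae strains was compared with that of the laboratory strain S288C by array comparative genomic hybridisation, a method in which the DNA of a strain and of a reference compete for the same spotted probes in different dyes. The strains were a plant isolate (10131), a cachaça strain (CPE7), a Jerez wine strain (GB-FlorC), a sake strain (Kyokai), a strain from masato, a cassava beverage (PE35M), a wine strain (T73) and an agave strain (Temohaya-26). Per the labels' protocols, each was grown in rich medium for 24 h at 28 °C, its DNA was cut with HinfI, and each comparison used duplicate arrays with the dyes exchanged. The deposited table held 1 column per strain, so the arrays and dye exchanges had already been combined by the authors and their spread was not used here. How the authors combined, filtered and normalised the arrays, and the genome build behind the probes, was not given in the sources used here.

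The deposited values were read as log2 ratios, although neither their log base nor their direction was stated. The most extreme values, -10.605 and 8.531, lay beyond the 4.82 that a log10 ratio of a 16-bit scanner can reach. Strain over S288C was taken as the likely direction, because the labels name the strain as channel 1 and S288C as channel 2, and because each column had its long tail at negative values on an array of S288C genes. The scale of each column was left as deposited. The deposited medians ran from -0.058 to 0.034, and each column was then centred on its own median, with no further normalisation. The robust SD of a column ran from 0.2135 (agave strain) to 0.427 (masato strain). The number of arrays limits the precision, and signal over background and the number of spots per gene were not analysed here.

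The table held 6178 open reading frames (ORFs), each with 1 value in each of the 7 strains and none missing. Of these, 5674 matched a locus tag of the R64 gene table and 504 did not, 12 of which matched an older synonym. Unmatched ORFs kept their systematic names and stayed in all tests that need no position. The R64 table was used for gene symbols, chromosomes, the order of neighbours and the distance class from a chromosome end, and none of its coordinates is given. Values of exactly 0 were more frequent than a smooth distribution gives in the plant strain, with 51 against 5.5, and numbered 5 to 19 in the other columns. Whether these are measured values or filled ones is not given in the sources used here.

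The size threshold per strain was a log2 ratio of 1, a 2-fold difference, with no p-value since each strain had a single column. For differences from S288C shared by the strains, limma 3.58.1 in R 4.3.3 fitted an intercept to the 7 columns per ORF with moderated variances (eBayes) and Benjamini-Hochberg adjustment at 0.05. S288C served as the single control there, so its own spread was left out, and the p-values measure the spread between the strains and treat the 7 columns as independent. The 2 wine strains were compared with the 5 other strains by a limma fit with 2 groups. A chromosome was singled out where its median differed by at least 0.2 from that of the others, and a stretch where the running median over 15 adjacent ORFs reached 0.5 in size. The share of ORFs past the threshold within 30 kb of a chromosome end was set against that in the interior by an exact two-sided sign-flip permutation test, whose smallest possible p is 0.0156. Gene lists were tested with camera at a preset correlation of 0.01 and described per strain by the percentile of their median among 10000 random lists of the same size. Of 28 lists, 26 had measured members, since the lists of 2-micron plasmid and mitochondrial genes had none in the deposited table. The list of 31 Ty transposon ORFs was written by systematic name after the data were seen.

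Groups, tests, thresholds, the other lists and the rule for named genes were set before the data were examined. The rule took the 5 lowest and 5 highest ORFs per strain without Ty ORFs, the 15 lowest and 10 highest ORFs of those that passed the shared test with the same sign in all strains, and the 5 largest non-overlapping differences each way for the wine strains where none passed. It also took up to 4 members of a list by the size of their mean and the 3 largest strain-specific ORFs. The tests were tried on simulated data. For the shared test over 6178 ORFs with 200 changed, 99.6% of differences of -4, 99.6% of -2, 89.6% of -1 and 96.0% of 1 were recovered, with a mean of 12.2 false calls. For the wine comparison these shares were 96.8%, 91.2%, 46.4% and 46.8%, with 7 false calls. The simulated values were independent between ORFs and between columns, with an equal shift in each changed column. Neighbouring ORFs and some columns of the real data were correlated, so these rates may not hold for them. Alternatives covered thresholds, centring, scaling, robust fits, omission of each strain, window sizes and distances, and, chosen after the data were seen, exact 0 as missing, ORFs with a position alone and subtraction of the running median.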

Results

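Array comparative genomic hybridisation compared the DNA of 7 S. cerevisiae strains with that of S288C, the laboratory strain whose genome the array represents. A low ratio is a weaker signal than that of S288C, and whether the gene is missing was not tested. The strains came from a plant, from traditional fermentations (cachaça, masato, agave and wine), from Jerez wine and from sake. Each strain had a single column of 6178 log2 ratios, strain over S288C (the likely direction), so values of a single strain have no replicate error. Neighbouring ORFs alternated in the sake strain, with a mean Spearman correlation of -0.0531 at odd and 0.215 at even distances up to 12 ORFs. The same means were 0.187 and 0.3 in the cachaça strain and 0.221 and 0.262 in the agave strain, and this bears on the single values of these strains. The local alternation (windows of 21 ORFs) followed that of the sake strain at r = 0.378 in the Jerez wine strain. It ran against that of the sake strain in the plant (-0.444) and masato (-0.576) strains. Single values of the Jerez wine, plant and masato strains may thus be affected as well. Values over the 7 strains are given as mean ± SD with the strains as replicates.

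The first question was which genes differ from S288C in each strain. The amino acid permease gene AGP3 had log2 ratios of -6.62 in the plant strain 10131, -6.85 in the masato strain PE35M and -6.96 in the Jerez wine strain GB-FlorC. SOR1, a sorbitol dehydrogenase gene, was at -6.05 in the plant strain, -5.69 in the cachaça strain CPE7 and -5.98 in the sake strain Kyokai, and its paralogue SOR2 was at -5.37, -5.35 and -4.86 in these strains. AIF1, which encodes a cell death effector, was at -5.91 in the cachaça strain and -5.97 in the sake strain. The copies of ASP3, the cell-wall asparaginase II gene, were among the lowest ORFs of the plant strain (ASP3-1, -5.59), the masato strain (ASP3-4, -5.56) and the wine strain T73 (ASP3-3, -3.42).

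ORFs lower than S288C by at least 1 numbered 100 in the plant strain, 70 in the cachaça strain, 122 in the Jerez wine strain, 99 in the sake strain, 176 in the masato strain, 77 in the wine strain and 114 in the agave strain Temohaya-26. Higher by at least 1 were 192, 59, 49, 54, 122, 57 and 10 ORFs in the same order. The lowest value of all was YER188W in the Jerez wine strain, at -10.60. In the sake strain the histone H2B gene HTB2 was at -9.17, against -0.65 to 0.42 in the other strains, and the allantoate permease gene DAL5 was at -5.80. Other ORFs of large size in the Jerez wine strain were YAR053W (-6.93), YHR212C (-6.85) and YAR060C (-6.57). The masato strain had ZNF1, a transcription factor gene, at -5.44, and the agave strain had SOR2 at -3.55, YOL160W at -3.41 and YOL163W at -3.26. Among the 5674 ORFs with a position, subtraction of the running median over 15 adjacent ORFs took the lower ORFs from 148 to 62 in the masato strain, 81 to 48 in the plant strain, 64 to 35 in the wine strain, 92 to 70 in the agave strain and 62 to 49 in the cachaça strain. The sake strain went from 85 to 86, and the Jerez wine strain then had the most, 93 from 105. With a threshold of 3 robust SDs of each strain the agave strain had the most lower ORFs, 186 against 93 in the masato strain.

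The highest values stood mostly in single strains. In the sake strain the Hsp70 gene SSA3 was at 8.53, RRN10, a subunit gene of an RNA polymerase I transcription factor, at 4.94, and the autophagy gene ATG8 at 4.17, while ATG8 was at -4.91 in the Jerez wine strain. All 4 ORFs of the sake strain at 2 or more lie among the 116 of the left arm of chromosome II, as do HTB2 and PIN4 (-9.17 and -4.99), a grouping noticed after the values were seen. Whether a fault of the array lies behind these values was not tested. YPL247C was at 8.23 and CAR2, the ornithine transaminase gene of arginine breakdown, at 3.89 in the cachaça strain. CIN10 and MDJ1, a mitochondrial chaperone gene, were at 4.82 and 4.81 in the Jerez wine strain, and YDR262W, SIF2 and PMT5 at 4.22, 4.20 and 4.09 in the masato strain. The values of the cachaça, Jerez wine and masato strains are likewise single values of combined columns. Whether an array fault or a gain of the gene lies behind them was not tested. The stress gene DDR48 was at 2.03 in the plant strain and 1.78 in the wine strain. The agave strain had no value above 1.67 (YDR094W). Among the 5674 ORFs with a position, subtraction of the running median over 15 adjacent ORFs took the higher ORFs from 171 to 19 in the plant strain, 49 to 33 in the cachaça strain, 49 to 29 in the sake strain, 103 to 16 in the masato strain, 50 to 26 in the wine strain and 46 to 41 in the Jerez wine strain, and from 7 up to 11 in the agave strain.

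**Figure D1:**
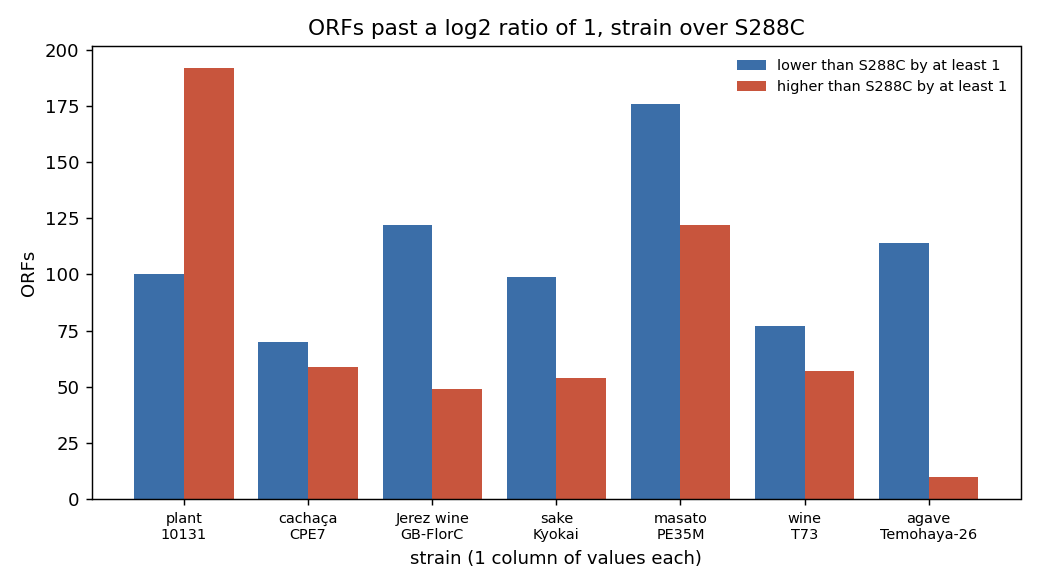
Bars give the number of ORFs (vertical axis) with a log2 ratio of -1 or less (blue) and of 1 or more (red) in each strain (horizontal axis, 1 column of values per strain). Among all 6178 ORFs the masato strain had 176 lower and the plant strain 192 higher ORFs, and among the 5674 with a position 148 and 171, which became 62 and 19 on subtraction of the running median.

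The next question was which differences from S288C the strains share. The lowest mean was that of YOL163W, at -4.52 ± 1.31 (SD, n = 7), with its neighbour YOL162W, which like it belongs to the Dal5 family of transporters, at -3.47 ± 0.58 and the sulfatase gene BDS1 beside them at -2.81 ± 0.55. The adjusted p values of these 3 neighbours on chromosome XV were 0.002, 6.4e-05 and 0.00013. On chromosome XII, ASP3-4 was at -4.37 ± 1.63, ASP3-1 at -3.56 ± 2.11 and ASP3-2 at -3.24 ± 2.05 (adjusted p 0.0075, 0.037 and 0.048), and the ORFs YLR159W and YLR161W between and beside the ASP3 copies at -2.60 ± 1.28 and -2.62 ± 1.20. CUP1-2, which encodes the copper-binding metallothionein, was at -2.57 ± 1.27 (adjusted p = 0.017).

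The limma fit found 66 of 6178 ORFs past the threshold, 53 lower and 13 higher, all with the same sign in 7 of 7 strains. At an unadjusted p under 0.05 there were 1039. Lower ORFs near the end of chromosome IV were SOR2, at -3.29 ± 2.07 (adjusted p = 0.047), and the alpha-glucoside permease gene MPH2, at -2.52 ± 1.29 (adjusted p = 0.021). On chromosome I, by their systematic names, were YAR047C (-3.39 ± 1.41), YAR061W (-3.38 ± 2.08), YAR060C (-3.19 ± 1.97) and YAL064W (-3.18 ± 1.41). By size in each strain, 8 ORFs were lower by at least 1 in all 7 strains, namely YAL064W, CUP1-1, YHR054C, CUP1-2, ASP3-4, YOL162W, YOL163W and BDS1, and no ORF was higher by at least 1 in 5 or more strains. The values of CUP1-1 and CUP1-2 were close in each strain, and both may come from a single mixed signal.

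The higher ORFs had smaller means. DIT1, a gene for the dityrosine layer of the spore wall, was at 0.90 ± 0.32 (adjusted p = 0.0099), MRP20, a mitochondrial ribosomal protein gene, at 0.79 ± 0.43 (0.038), HPT1, a purine salvage gene, at 0.75 ± 0.43 (0.044) and ADE8, a purine synthesis gene, at 0.70 ± 0.32 (0.023). All 4 lie close together on chromosome IV. YGL132W (0.66 ± 0.26), YKL091C (0.65 ± 0.33), PTC4 (0.62 ± 0.28), YLR162W (0.60 ± 0.33), NAB2 (0.60 ± 0.21) and MUD1 (0.55 ± 0.26) followed. The count of 66 was 21 without the masato strain, 33 without the plant strain, 36 without the wine strain, 37 without the agave strain, 39 without the cachaça strain and 43 without the Jerez wine strain, and 98 without the sake strain. Higher ORFs among these ran from 1 without the wine strain to 20 without the sake strain. Over the 5674 ORFs with a position alone it was 52, and after subtraction of the running median from these it was 10, 1 of them higher (YLR162W). Of the 55 calls with a position, the 45 lost in this way kept their sign while their median size went from 0.79 to 0.40 (median standard error 0.113 and 0.117), and the size of the 10 kept went from 2.25 to 1.81. Several large calls were lost with little change in size, among them ASP3-1 (-3.56 to -3.58, adjusted p = 0.15 after), ASP3-2 (-3.24 to -3.18, 0.17), YLR159W (-2.60 to -2.49, 0.078), CUP1-2 (-2.57 to -2.49, 0.1), CUP1-1 (-2.51 to -2.42, 0.091) and PRM8 (-1.55 to -1.56, 0.11). SOR2 (-3.29 to -2.95, 0.16), MPH2 (-2.52 to -2.18, 0.093), YAR061W (-3.38 to -3.07, 0.2) and YAL064W (-3.18 to -2.92, 0.093) were lost as well. The limma p-values treat the 7 columns as independent, although running medians of the plant, masato and wine strains correlated at 0.831 to 0.89. Signals of near-identical copies can mix on an array, and the copies of ASP3 still read -0.53, -0.18, -2.06 and -4.87 in the sake strain.

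**Figure D2:**
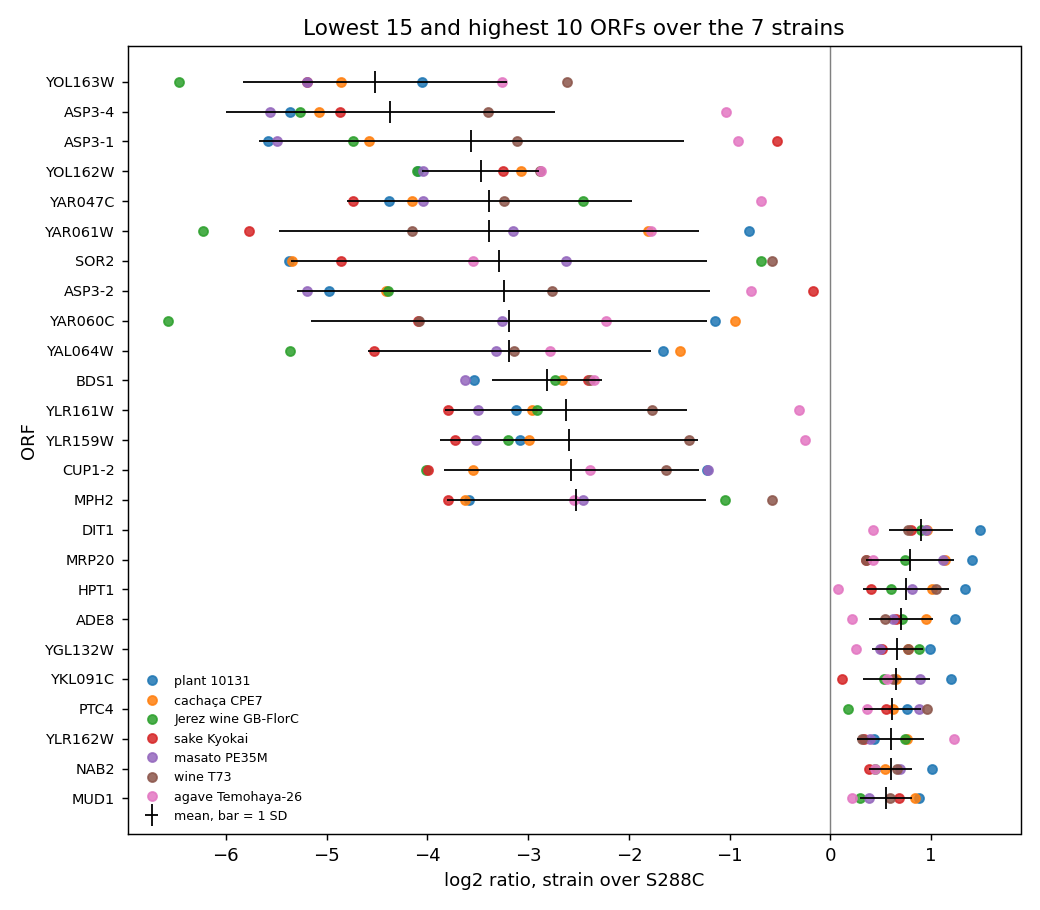
Points give the log2 ratio (horizontal axis) of each of the 7 strains for the 15 lowest and 10 highest ORFs of the shared test (vertical axis), with the mean as a tick and 1 SD as a bar. YOL162W ran from -4.10 to -2.87 and BDS1 from -3.63 to -2.35, while ASP3-1 ran from -5.59 to -0.53.

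Gene families that vary between yeasts, and control lists of genes of core cell functions, were then compared with all other ORFs. The asparaginase II genes had a median of mean log2 ratios of -3.40, with 3 of 4 members lower over all ORFs and 4 adjusted over the list alone. ASP3-3 in the plant strain was deposited at exactly 0 (0.02 after centring), while the other copies there were between -5.59 and -4.97. Its adjusted p was 0.059, and with exact 0 as missing it was 0.024 over 6 strains, so that all 4 passed. The metallothionein genes CUP1-1 (-2.51 ± 1.18) and CUP1-2 (-2.57 ± 1.27) were both lower by either adjustment. Their values were close in each strain, with an estimated correlation of 1, so they may be a single mixed signal rather than 2 separate results. Of the sodium ATPase genes, which export sodium, ENA1 (-1.27 ± 0.62) and ENA2 (-1.32 ± 0.68) were lower over all ORFs and all 3 adjusted over the list alone. The estimated correlation of the sodium ATPase genes was 0.97, so they may not be separate results either. Aryl alcohol dehydrogenase genes had a median of -0.94, with 3 of 6 lower over all ORFs, AAD15 (-1.57 ± 0.58) and AAD3 (-1.13 ± 0.64) among them, and 6 adjusted over the list alone.

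Camera with the preset correlation placed 15 of 26 lists past the threshold, all lower, and with an estimated correlation it placed only the aryl alcohol dehydrogenases there (adjusted p = 6.6e-08 preset, adjusted p = 0.026 with an estimated correlation). The lists of asparaginase II (preset adjusted p = 1.2e-06), metallothionein (0.00018), sodium ATPases (2.4e-05), hexose transport (1.8e-06), maltose and isomaltose use (0.00026), COS family (2.6e-06), iron uptake (0.0031), allantoin use (0.034) and Ty ORFs (3e-12) each had an adjusted p = 0.12 with an estimated correlation. That p was 0.067 for the flocculins and adhesins (preset 7.1e-05), 0.33 for the seripauperins (4.5e-07), 0.13 for the DUP240 family (7.2e-05), 0.26 for the Y' helicases (0.0063) and 0.23 for thiamine and vitamin B6 (0.00028). The allantoin list did not pass without the cachaça, Jerez wine or masato strain (adjusted p = 0.0523, 0.0915 and 0.0508).

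Of 20 hexose transport genes 1 was lower over all ORFs, HXT16 (-1.75 ± 1.06), and 9 were lower adjusted over the list alone, while HXT15 (-1.55 ± 1.10) did not pass over all ORFs. Of 13 maltose and isomaltose genes, MPH2 and MPH3 (-1.57 ± 0.82) were lower, and 8 were lower and 1 higher adjusted over the list alone. FLO1 (-0.96 ± 0.29) and FLO5 (-0.56 ± 0.20), cell-surface flocculins, were lower among 9 flocculins and adhesins (3 adjusted over the list alone). Among 23 seripauperins, PAU15 (-0.79 ± 0.25) and PAU22 (-0.54 ± 0.28) were lower (6 adjusted over the list alone). COS7 (-0.66 ± 0.29) and COS5 (-0.62 ± 0.23) were lower among 11 COS genes (8 adjusted over the list alone), and PRM8 (-1.55 ± 0.95) among 10 DUP240 genes (4 adjusted over the list alone). No member passed over all ORFs among 17 iron uptake genes (3 lower and 1 higher adjusted over the list alone), 11 allantoin genes (0), 7 Y' helicases (0), 10 thiamine and vitamin B6 genes (1 lower) and 31 Ty ORFs (20 lower). The Ty list was drawn up after the data were seen.

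The other lists did not pass with the preset correlation. Their adjusted p values and medians were 0.15 and 0.15 for galactose use, 0.87 and 0.05 for biotin, 0.51 and -0.20 for arsenic resistance, 0.051 and 0.13 for amino acid permeases, 0.13 and 0.02 for phosphate uptake and phosphatases, and 0.72 and -0.02 for drug efflux. For the control lists they were 0.34 and 0.04 for glycolysis and ethanol, 0.52 and 0.03 for ergosterol synthesis, 0.62 and -0.04 for the proteasome, 0.23 and 0.08 for histones and 0.32 and 0.03 for cytosolic ribosomal proteins. The mean and the median differed in sign for amino acid permeases (mean -0.03), phosphate uptake (mean -0.12) and histones (mean -0.04), and camera put amino acid permeases and histones higher and phosphate uptake lower. Amino acid permeases passed without the plant, masato or wine strain (adjusted p = 0.0136, 0.0184 and 0.0445) and phosphate uptake without the cachaça strain (0.0427). None of the members of these lists passed over all ORFs, and adjusted over the list alone 1 biotin gene was higher and 2 phosphate genes were lower.

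**Figure D3:**
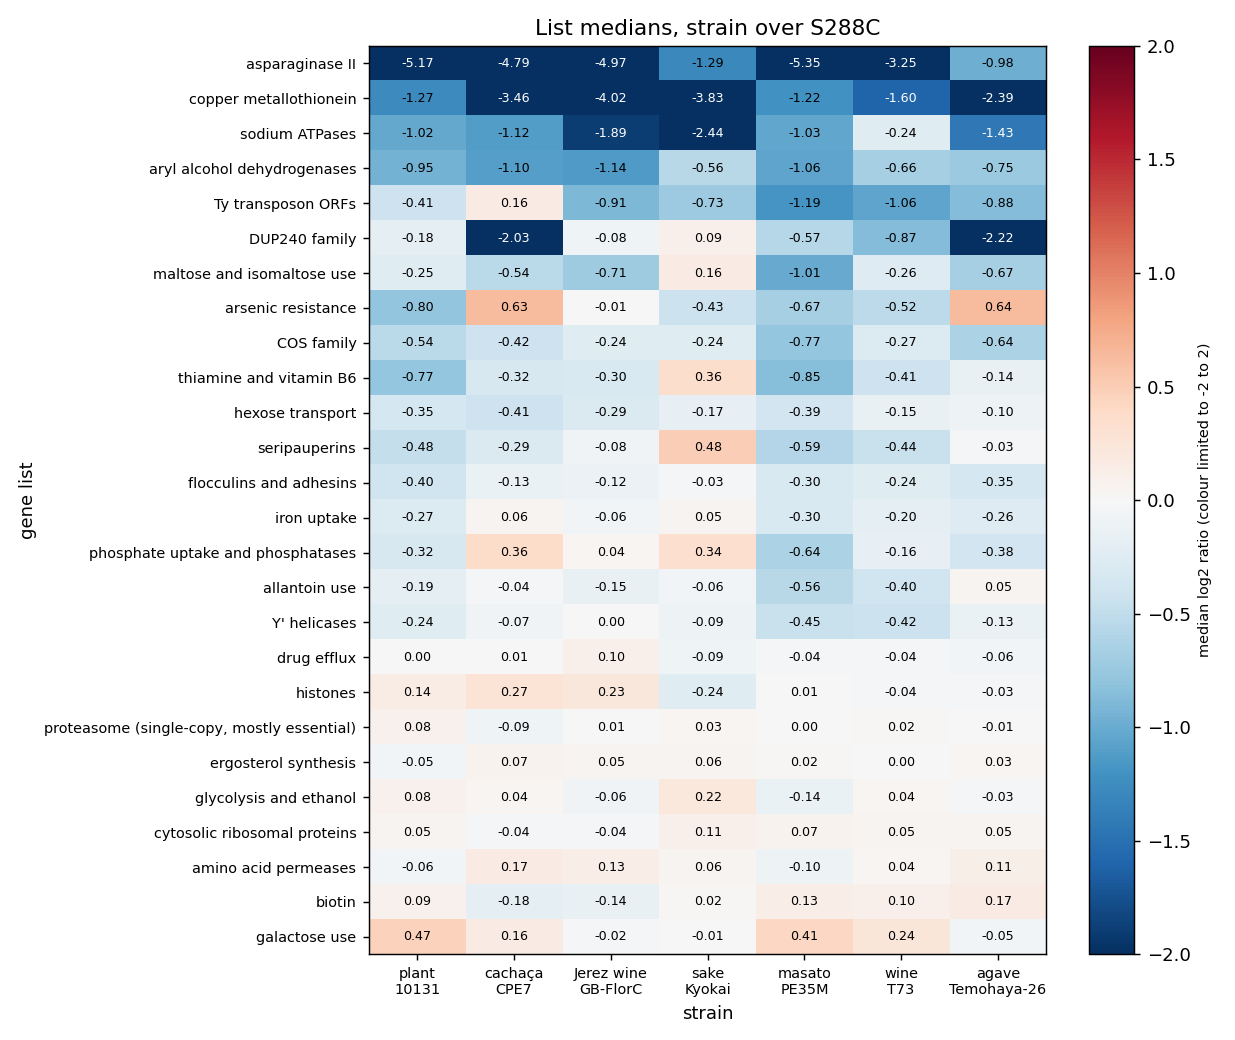
Each cell gives the median log2 ratio of a gene list (vertical axis) in a strain (horizontal axis), with blue below 0, red above 0 and the colour limited to -2 to 2. Asparaginase II ran from -5.35 in the masato strain to -0.98 in the agave strain, and the DUP240 family from -2.22 in the agave strain to 0.09 in the sake strain.

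Chromosome ends were set against the interior because they hold many of the variable gene families of this yeast. Within 30 kb of an end, 13.2 ± 4.34% (SD, n = 7) of 371 ORFs were past the threshold, against 2.07 ± 0.976% of 5303 ORFs farther away. The difference of 11.2 ± 3.59 percentage points was above 0 in 7 of 7 strains (exact two-sided sign-flip permutation test, p = 0.0156, the smallest it can give). Lower ORFs made up 12.5 ± 4.65% at the ends and 0.843 ± 0.337% in the interior (exact sign-flip p = 0.0156), and the share past the threshold in either direction at the ends ran from 8.62% in the wine strain to 21.3% in the masato strain. Higher ORFs made up 0.770 ± 0.815% and 1.23 ± 1.01% (exact sign-flip p = 0.422). The sign-flip test treats the 7 strains as independent, although all share the S288C DNA. Running medians of the plant, masato and wine strains also correlated at 0.831 to 0.89. Of the ORFs lower over all strains, 43 had a position and 24 of these lay within 30 kb of an end, while none of the 12 higher ORFs with a position did.

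Whole chromosomes were compared to look for shifts that all their ORFs share. Chromosome I of the sake strain had a median of 0.69, with 86.4% of its 88 ORFs above 0, and chromosome III of the Jerez wine strain a median of 0.30, with 86.9% of 153 ORFs above 0. In the masato strain chromosomes I (-0.66), VI (-0.61), IX (-0.46), III (-0.42) and VIII (-0.34) were lower and chromosomes IV (0.19) and XII (0.30) higher. Of the ORFs there, 2.27% were above 0 on chromosome I, 72.4% on IV and 77.9% on XII. Chromosome IV also held a lower stretch at its end (COS7 to LRG1, median -1.54), so its median is not a shift that all its ORFs share. In the plant strain chromosomes III (-0.35), IX (-0.31), I (-0.30), VI (-0.28) and VIII (-0.21) were lower, in the wine strain chromosomes I (-0.47), VI (-0.39), III (-0.29) and IX (-0.22), and in the agave strain chromosomes I (-0.28) and VI (-0.24). Chromosome I of the cachaça strain, at 0.20, was no longer singled out with a trimmed mean.

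The relation of the chromosome medians to chromosome length was examined after the medians were seen, and r passed the adjustment in 4 of the 7 strains. Across the 16 chromosomes of a strain, Pearson's r was 0.885 in the plant strain (Spearman's rho 0.929), 0.928 in the masato strain (0.979), 0.889 in the wine strain (0.953) and 0.755 in the agave strain (0.788). Adjusted over the 7 strains, the permutation p values of r were 7e-05, 3.5e-05, 3.5e-05 and 6e-04, from 3e-05, 1e-05, 1e-05 and 0.00034 unadjusted, where 1e-05 is the smallest that the 100000 resamples give. The adjusted p values of rho were 4.7e-05, 3.5e-05, 3.5e-05 and 0.00084. Without chromosomes IV and I, r was 0.934, 0.969, 0.946 and 0.698. In the cachaça, Jerez wine and sake strains r was -0.44, 0.19 and -0.47 (adjusted permutation p = 0.1, 0.47 and 0.091), and rho was -0.25, 0.585 and -0.447 (adjusted 0.35, 0.028 and 0.098), so that in the Jerez wine strain rho passed and r did not. Without chromosomes IV and I, r was -0.311, 0.0253 and -0.286 there.

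**Figure D4:**
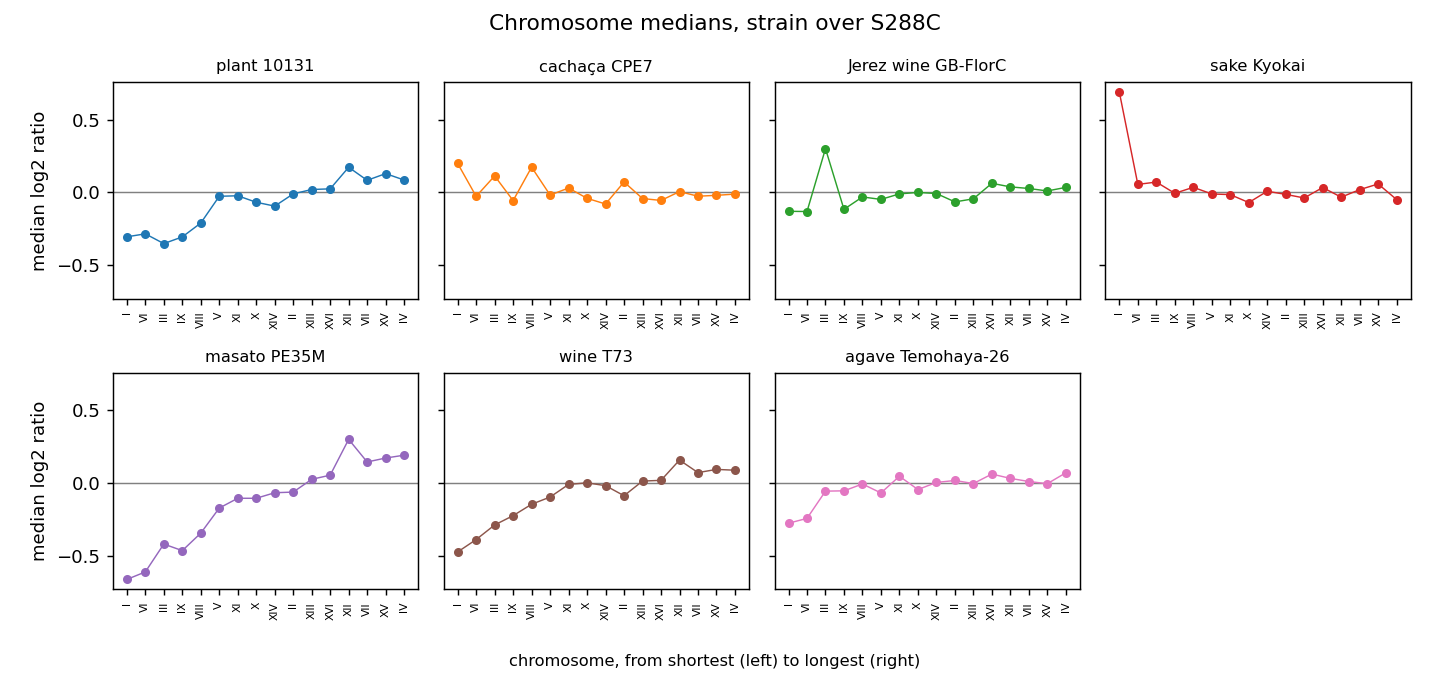
Each panel gives the median log2 ratio of the ORFs of a chromosome (vertical axis) for 1 strain, with the 16 chromosomes from shortest to longest (horizontal axis). The sake strain had chromosome I at 0.69, and the masato strain ran from -0.66 on chromosome I to 0.30 on chromosome XII.

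Runs of adjacent ORFs were compared to find segments that differ together, and those named were chosen after their values were seen. In the sake strain a run of 78 ORFs from PAU8 to DFP2 covered most of chromosome I, with a median of 0.71. The cachaça strain had 15 ORFs from CTO1 to RHB1 on chromosome III at a median of 1.12 and 11 ORFs from AAD15 to HPF1 on chromosome XV at -2.66. A lower stretch from AAD15 was also found in the plant (the same 11 ORFs, -0.96), masato (-0.62), wine (-0.72) and agave (-0.63) strains. In the Jerez wine strain the 14 ORFs from YFL068W to DAK2 on chromosome VI had a median of -0.86 and the 13 ORFs from FRE3 to PAU21 on chromosome XV one of -0.88. Lower stretches from YFL068W were also found in the plant (-0.61), masato (-0.81) and wine (-0.74) strains. The agave strain had 16 ORFs from CDC15 to PHO11 on chromosome I at -1.10, 9 ORFs from APM2 to PRS3 on chromosome VIII at -0.91 and 15 ORFs from RSM7 to YJR128W on chromosome X at -0.69. Lower stretches that end at PHO11 were also found in the wine (-0.57) and masato (-0.77) strains.

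The plant strain had 23 higher and 25 lower stretches over 688 ORFs, the masato strain 20 and 33 over 848 ORFs, and the wine strain 9 and 13 over 209 ORFs. Stretches of the 3 strains overlapped on chromosome IV, where SAC7 to RRP17 had a median of 1.21 in the plant strain, SPT3 to STE14 one of 0.89 in the masato strain and IAT4 to DFM1 one of 0.83 in the wine strain. They also overlapped on chromosome XII, where YLR126C to YLR152C had a median of 1.14 in the plant strain, TML25 to RNH203 one of 0.91 in the masato strain and DIP2 to STM1 one of 0.76 in the wine strain. The cachaça strain had 5 higher and 2 lower stretches, the Jerez wine strain 0 and 2, the sake strain 1 and 0 and the agave strain 0 and 5. With a limit of 0.3 the number of stretches was 94 in the plant strain, 110 in the masato strain and 51 in the sake strain.

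**Figure D5:**
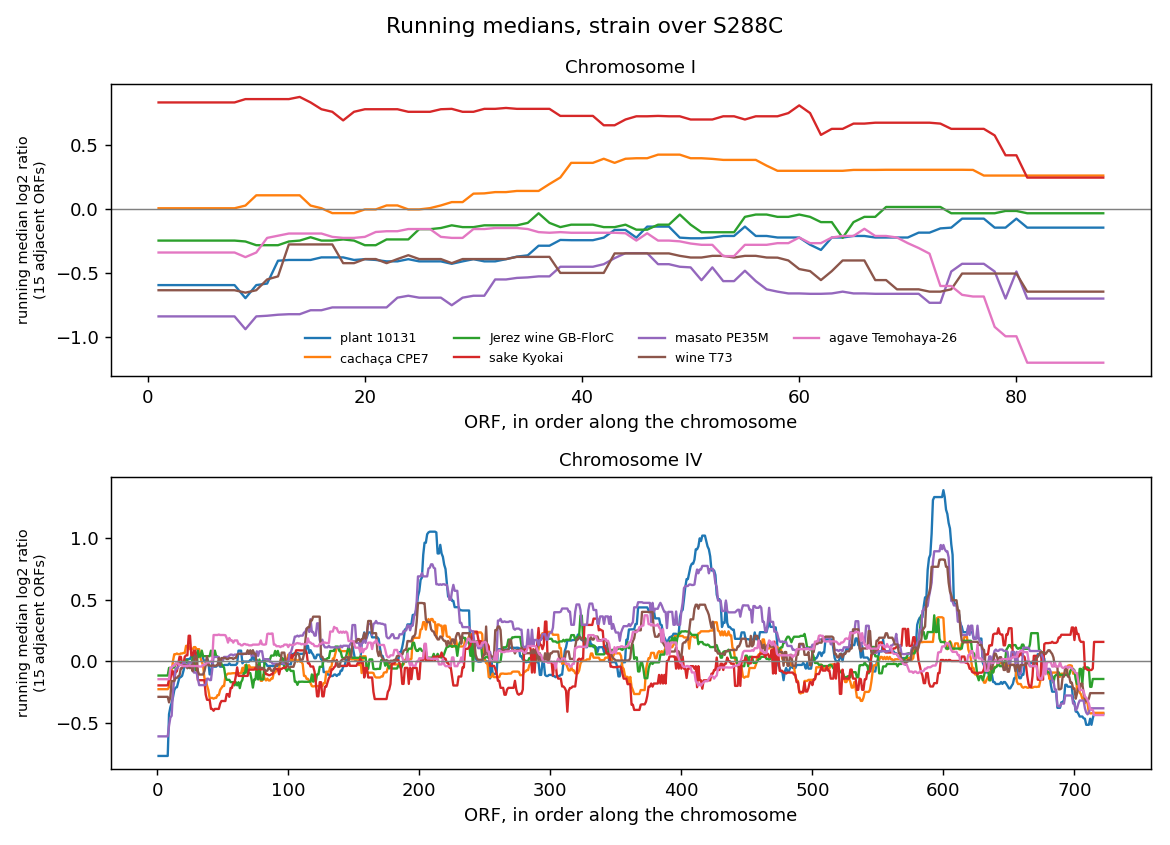
Lines give the running median log2 ratio over 15 adjacent ORFs (vertical axis) along chromosomes I and IV (horizontal axis, ORFs in order) for the 7 strains. On chromosome I the sake strain lies above the others along most of its length (median 0.69), and on chromosome IV the plant, masato and wine strains share a peak (stretch medians 1.21, 0.89 and 0.83).

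Wine is the only origin shared by a pair of strains, which allowed the T73 and Jerez wine strains to be set against the 5 others. SOR2 had a mean of -0.63 in the wine strains and of -4.35 ± 1.22 (SD, n = 5) in the others, a difference of 3.71. MPH2, its neighbour, was at -0.81 and -3.20 ± 0.65, a difference of 2.39. YJR157W differed by 3.41, YJL218W by 2.19, YNR065C by -1.16 and the hexose transporter gene HXT9 by -0.75. The other 4 differences came mostly from the Jerez wine strain. COS1 was at 3.26 there and 0.66 in T73 (others -0.46 ± 0.56), the photolyase gene PHR1 at -3.77 and -0.44 (others -0.20 ± 0.24), the thioesterase gene TES1 at -1.32 and -0.51 (others 0.10 ± 0.33) and SPO71 at -1.39 and -0.40 (others -0.04 ± 0.09).

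None of these differences passed the adjustment, and the limma fit called 0 of 6178 ORFs (smallest adjusted p = 1), with 72 at an unadjusted p under 0.05. The unadjusted p was 0.000707 for SOR2 and 0.000329 for MPH2. The groups did not overlap for 187 ORFs, 3.03% of all, where chance gives 9.52% if the columns are interchangeable. The other choices of 2 strains gave 0 to 2 ORFs past the threshold. Their non-overlapping ORFs ran from 198 (cachaça and wine strains) to 1630 (plant and masato strains), so the columns were not interchangeable. The wine pair lies across the split of columns given by the sign patterns below, and its low count is thus no result about wine. Without the wine strain T73, which leaves the Jerez wine strain alone and assumes that it varies like the others, 19 ORFs passed.

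The similarity of the strains was compared across ORFs, which are not independent replicates, after the mean of the 7 strains was removed so that the shared S288C reference cancels. The most similar pairs were the plant and masato strains (r = 0.487), the masato and wine strains (0.353) and the plant and wine strains (0.282). Wine strain T73 and the Jerez wine strain had r = -0.41, rank 15 of 21 pairs, where unrelated columns give -0.167. T73 had similar values with the cachaça (-0.441) and sake (-0.45) strains. The Jerez wine strain had -0.444 with the plant strain, but -0.231 with the masato and -0.207 with the agave strain. The sign patterns below set the cachaça, Jerez wine and sake columns apart from the rest, and the wine pair lies across that split. Its r thus does not tell how alike the wine strains are in gene content. The masato and sake strains were the least similar (r = -0.599). The plant, masato and wine strains also had running medians that correlated at 0.831 to 0.89. After subtraction of the running median their pairs still ranked highest (r = 0.399, 0.327 and 0.305 in the same order). The local alternation of the masato strain ran against that of the sake strain (r = -0.576). Patterns along the columns may thus add to these correlations, and the share of the alternation was not tested. Of the lower ORFs, pairs of strains shared 26 (plant and wine strains) to 71 (Jerez wine and masato strains), against 0.872 to 3.48 for independent lists, and part of the excess may come from the shared S288C DNA.

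Some ORFs differed in a single strain, with all others within 0.5 of 0. The Jerez wine strain had 28 of these, among them the ferric reductase gene FRE5 (-4.82), PHR1 (-3.77) and CIN10 (4.82), and the sake strain 19, among them PIN4 (-4.99), DOA1 (-4.57) and LDB7 (2.42). The plant strain had 11, with YIL168W at -4.66, the flocculin gene FLO10 at -1.71 and RSC8 at 1.40. The cachaça strain had 12, with the siderophore transporter gene ENB1 at -2.88, STP3 at 1.88 and YGR051C at 1.87, and the agave strain 12, with IRC4 at -2.72, MIC26 at -1.28 and YLF2 at -1.25. The masato strain had 5, with SIF2 at 4.20, PUT7 at 1.26 and FLC2 at 1.17, and the wine strain 8, with DRS2 at -1.40, PAM1 at 1.28 and CYK3 at 1.24. With the others within 0.8 these numbers were 55 for the Jerez wine, 45 for the sake, 58 for the plant, 25 for the cachaça, 31 for the agave, 35 for the masato and 25 for the wine strain.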

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

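A strain was taken to lie far from the others where the gap between it and its nearest neighbour made up more of the whole range than Dixon's 95% limit allows. Of 70 quantities looked at, chosen after the data were seen, 1 did so, where chance gives about 3.5. The median of chromosome XVI in the cachaça strain was -0.055, against 0.018 to 0.0625 in the other 6 strains.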

How the results depend on the processing

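The subtraction of the running median, the treatment of exact 0 as missing and the restriction to ORFs with a position were chosen after the data were seen. The 25 named ORFs of the shared test kept their direction in all 369 values over 15 alternatives, and 132 of these values were no longer past the threshold. The kept direction is no test in most of these, since the ORFs were picked for the same sign in all 7 strains. Omission of a strain, averaging, scaling or another variance fit cannot turn the sign of their mean. The 21 shifts of single chromosomes moved by less than the spread between strains in all 42 values. With values as deposited, with exact 0 as missing, with Ty ORFs left out and with ORFs with a position alone, no count moved by over 1.5 times. The difference between chromosome ends and the interior passed at 15 and 50 kb, at a threshold of 0.58 and without Ty ORFs. The median over several probes and the restriction to ORFs measured in all 7 strains were not run, since each ORF has 1 value and none is missing. No paired analysis was possible because each group holds a single column.

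In the order plant, cachaça, Jerez wine, sake, masato, wine and agave strain, a threshold of 0.58 gave 427, 202, 223, 332, 654, 312 and 215 lower and 613, 248, 197, 370, 574, 394 and 50 higher ORFs. A threshold of 1.5 gave 44 lower and 40 higher in the plant strain, 19 higher in the cachaça strain, 80 and 13 in the Jerez wine strain, 16 higher in the sake strain, 75 and 9 in the masato strain, 26 and 7 in the wine strain and 70 and 2 in the agave strain. With 3 robust SDs of the strain there were 126 higher in the plant strain, 113 higher in the Jerez wine strain, 93 lower and 24 higher in the masato strain and 186 and 35 in the agave strain. With the running median subtracted there were 48 lower and 19 higher in the plant strain, 33 higher in the cachaça strain, 29 higher in the sake strain, 62 and 16 in the masato strain, 35 and 26 in the wine strain and 70 lower in the agave strain. The 504 ORFs without a position drop out there, which by itself leaves 81 lower and 171 higher in the plant strain and 148 and 103 in the masato strain.

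For the shared test, columns scaled to an equal spread gave 23 higher ORFs, the wine strains averaged gave 6 higher, a test against a size of 0.2 gave 22 lower and 1 higher, and the running median subtracted gave 9 lower and 1 higher, against 41 and 11 over the same ORFs before. Omission of each strain gave 18 to 78 lower and 1 to 20 higher ORFs, with fewer columns in the fit. Of the 66 ORFs, 59 were called with scaled columns, 58 with the robust fit and 21 without the masato strain. The wine comparison gave 0 to 19 ORFs without 1 strain, the 19 without T73. The trimmed mean left 0 chromosomes singled out in the cachaça strain. A window of 25 ORFs gave 2 stretches in the cachaça strain, 0 in the Jerez wine strain, 10 in the wine strain and 2 in the agave strain, and a limit of 0.3 gave 94, 55, 22, 51, 110, 75 and 23 in the order above. Gene lists past the threshold numbered 1 with an estimated correlation and 14 to 16 without 1 strain. ORFs past the threshold in a single strain, with the others within 0.8, numbered 58, 25, 55, 45, 35, 25 and 31 in that order. Apart from the smaller sets named, the cause was not tested. The rank of the pair of wine strains stayed between 15 and 18. Signal over background was not analysed here, so its limit on small differences is unknown.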

Other observations

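The tests of S288C copy number and of chromosome I of the sake strain were chosen after the results were seen. Several lists differed between strains in a way that their means over the strains do not show, and these differences between strains were not tested. The arsenic resistance genes ARR1, ARR2 and ARR3 had medians of 0.63 in the cachaça strain and 0.64 in the agave strain, above 99.78% and 99.98% of random lists. Their medians were -0.80 in the plant, -0.67 in the masato, -0.52 in the wine, -0.43 in the sake and -0.01 in the Jerez wine strain. Random lists ignore position and correlation, while these genes had an estimated correlation of 0.83, so the percentiles may overstate how unusual the medians are. The DUP240 membrane protein genes had medians of -2.03 in the cachaça strain and -2.22 in the agave strain, with 6 and 7 of 10 members lower by at least 1, and 0.09 in the sake strain. Ty transposon ORFs had a median of 0.16 in the cachaça strain and -0.41 to -1.19 in the others. The seripauperins and the thiamine and vitamin B6 genes had medians of 0.48 and 0.36 in the sake strain, and of -0.59 and -0.85 in the masato strain. MAL11 and MAL13, maltose transporter and regulator genes, were at -4.39 and -6.12 in the Jerez wine strain, -4.19 and -5.25 in the masato strain and at -2.70 and -2.44 in the agave strain, while in the other 4 strains both lay between -0.36 and 0.21.

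Long stretches shifted at the same places in the plant, masato and wine strains, whose running medians correlated at 0.831 to 0.89, against -0.262 to 0.461 for the other 18 pairs. All pairs share the S288C DNA, and the correlation that this alone gives was not estimated. Distance from the chromosome ends alone was argued against, since the correlation of the masato and plant strains was 0.89 before and 0.853 after removal of the medians of 10 distance classes. Copy number of S288C as the sole source was argued against, since it would shift the same stretches alike in every column. The cachaça, Jerez wine and sake strains correlated with the masato strain at only 0.334, 0.373 and -0.251. Removal of the mean of the strains cancels the shared S288C DNA. The plant and masato, masato and wine, and plant and wine strains then still had r = 0.487, 0.353 and 0.282 across ORFs. Whether S288C adds a part to the shared stretches stays open. Separate copy-number changes, growth phase, base composition and a biological difference between the strains may each remain as explanations and were not tested.

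Values of the sake strain alternated between neighbouring ORFs, with a mean Spearman correlation of -0.0531 at odd and 0.215 at even distances up to 12 ORFs, against 0.187 and 0.3 in the cachaça strain. The strand of the ORF is unlikely as the source, since neighbours on the same strand correlated at 0.0253. The local alternation of the sake and cachaça strains, in the order of systematic names, correlated at 0.749 over windows of 21 ORFs. An effect of the order of the ORFs on the array may be at work. Any cause tied to the ORFs that these columns share could give this value, so it cannot tell which. With the Jerez wine, plant, agave and masato strains the value was 0.378, -0.444, -0.534 and -0.576, and with T73 it was -0.000977, so the pattern of T73 was unrelated to that of the sake strain. Positions of probes on the array were not analysed here, and no biological explanation was tested.

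Chromosome I of the sake strain was higher along most of its length, while its running median was 0.243 from YAT1 to PHO11 at the right end. The medians of its 3 equal parts were 0.778, 0.721 and 0.572, and those of its odd and even ORFs 0.67 and 0.751. A shift of all small chromosomes was argued against by the medians of chromosomes VI, III and IX, of which the highest was 0.071. An extra copy of chromosome I in this strain may be the reason, as a hypothesis found on the same data, and other technical explanations stay open as well. A karyotype or an independent measure of the dosage of this chromosome would bear on it, and neither was used here.

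Signs of the strains were also turned to see whether chance alone gives as many shared differences. Of the 64 sign patterns of the 7 strains, 2 gave at least the 66 ORFs found, the real pattern among them, which excludes chance at the 5% limit only if the 7 columns are independent. The running medians of the plant, masato and wine strains, which correlated at 0.831 to 0.89, go against that, so chance is not taken as excluded. The other gave 724 ORFs with the cachaça, Jerez wine and sake strains turned, which points to a structure of the samples that sets these 3 columns apart from the other 4.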
